A study of Mus musculus with 4 samples.

How the data were processed

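The series holds 4 Affymetrix Mouse Genome 430 2.0 arrays, a 1-colour array on which each gene is read by 1 or more probe sets. Per the labels' protocols, total RNA of the gastric corpus epithelium was purified, pooled from 3 mice for each condition, amplified and labelled with biotin. The mice were 6 weeks old and wild type, of the strains C57BL/6, BALB/c and FVB/N, and the labels tie neither strain nor sex to an array. Tamoxifen was injected at 5 mg per 20 g of body weight, dissolved in 90% sunflower oil with 10% ethanol. Injection went on for 1 or 3 days, and the labels do not say which array had which. The groups, taken from the treatment and time labels, were vehicle at 2.5 days and tamoxifen after 12 hours, after 2.5 days and after 4.5 days, with 1 array each.

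The deposited values are log2 expression of 45101 probe sets, made with RMA in Partek per the submitters' processing notes, whose versions are not given in the sources used here. RMA corrects background, normalizes all arrays to 1 distribution by quantiles and summarizes the probes of a probe set. The log base is stated by no label and was inferred from the values, which ran from 2.06 to 14.85. Quantile normalization sets the overall distributions equal, so a shift shared by most genes would not be seen. RMA compresses differences of dim genes and of genes near the top of the scale.

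Control probe sets, 64 in number, were left out of the gene counts. By the platform annotation 34958 probe sets had exactly 1 gene symbol, 932 had several and 9211 had none, controls included. Probe sets with several or none were not used for named genes. Gene IDs of 34741 named probe sets matched the current annotation, and no symbol needed updating. This gave 18193 genes, 9010 of them with several probe sets. A gene was read from its probe set with the highest mean over the 4 arrays. It entered a count of expressed genes if the brighter of the 2 arrays compared was at or above that array's median over all probe sets. No genome coordinates are given, since the array values carry none.

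With 1 array per group no test across samples can be made. Differences of log2 values were taken for each tamoxifen array against vehicle and for the steps from 12 hours to 2.5 days and from 2.5 to 4.5 days, and genes at or past 2-fold were counted in each direction. Technical error was gauged from hybridisation and poly-A control probe sets and from the range over a gene's probe sets above the array median. A further gauge was the closest pair of arrays, 2 pools taken at different times. That pair holds differences between mice and between times as well as technical error. The number of arrays limits the precision, and variation between mice does not enter the other gauges.

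Before the data were examined, 43 gene lists were fixed: 21 of cell types, including cell types and tissues other than the gastric glands, and 22 of pathways and gene classes. Of their members 468 were measured and 42 are not analysed here. A list was described by the median difference of its members at all levels, the order-statistic 95% interval of that median over genes, and the percentile of the median among 10000 random lists of the same size, matched on mean expression in 20 bins. These percentiles describe these arrays and are not p-values. After the data were seen, 3 more lists (pancreatic islet, a second acinar and a second squamous list) and wide lists of 53 pancreatic and 83 squamous genes were drawn up. Part of each wide list was taken by the start of the gene symbol, so the pancreatic one also holds serine protease genes known from other tissues.

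The rule for named genes was also fixed before the data were examined. It took the 10 largest differences in each direction for each tamoxifen array against vehicle, the 5 largest in each direction for the steps between tamoxifen arrays, and up to 4 members of each list with the largest absolute difference. A gene was to be named as conflicting if its probe sets disagreed by 2-fold in each direction. Among probe sets above the array median no gene named by the rule did so, and dimmer probe sets were not checked. Predicted genes and clones without a gene name were counted but not named. A few other members of the lists are named as counterexamples or as the best known genes of a cell type, and these were chosen after their values were seen.

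Because 1 vehicle array served 3 comparisons, overlaps of their genes were set beside the overlap of independent lists and beside 100 simulations of unchanged arrays. All simulated arrays, the shared one included, took their noise from the closest pair, with an SD of 0.11 per array. The measured vehicle array did not enter these simulations. On simulated arrays with 200 changed genes, the 2-fold rule at 12 hours against vehicle recovered 4.00% of genes changed 1.5-fold, 50.0% of those changed 2-fold and 100% of those changed 3-fold. It took 0.51% of unchanged genes past 2-fold there, 0.37% at 2.5 days and 0.42% at 4.5 days. Of 100 random lists of 15 genes, 5, 6 and 3 fell outside percentiles 2.5 to 97.5 in the 3 comparisons.

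Alternatives fixed before the data were examined were a repeated quantile normalization, removal of a loess trend of difference against level (span 0.40), no filter on dim genes or a filter at the 75th percentile, and thresholds of 1.5-fold and 3-fold. Others were the mean of all probe sets of a gene, the probe set with the median absolute difference, leaving out probe sets ending in _s_at or _x_at, unmatched random lists, and expressed members alone. The probe set with the median absolute difference was taken at any level, dim ones included. Of 2 probe sets it was the one with the smaller absolute difference. Added after the data were seen were leaving out the wide pancreatic and squamous lists, leaving out genes at least 2-fold apart on the 12-hour array from each of the other 3, and choosing probe sets without the 12-hour array. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.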

Results

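By the labels, gene expression was measured in the epithelium of the gastric corpus of wild-type mice. The corpus is the acid-secreting part of the stomach, whose glands hold parietal, chief, mucous neck, surface mucous and endocrine cells. Tamoxifen, a selective estrogen receptor modulator, was injected into the peritoneum of 6-week-old mice at 5 mg per 20 g of body weight. The stated aim of the treatment was to induce SPEM (spasmolytic polypeptide-expressing metaplasia), a state in which corpus glands carry transcripts typical of mucous neck cells. The 4 arrays held vehicle at 2.5 days and tamoxifen after 12 hours, after 2.5 days and after 4.5 days, and each array measured RNA pooled from 3 mice. Each group was therefore 1 array, so the spread between mice could not be estimated and no p-value is given. Vehicle was measured at 2.5 days only, and the same array served all 3 comparisons with tamoxifen.

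Expression is given as log2 RMA values, and differences are on the log2 scale, so that 1 is 2-fold. The medians of the 4 arrays lay between 5.30 and 5.34, and 10 to 15 genes per array lay above 14, near the top of the scale. Between tamoxifen arrays and vehicle, 18 hybridisation controls differed with an SD of 0.08 to 0.10. Their mean differences were 0.04, -0.13 and -0.16 at 12 hours, 2.5 and 4.5 days, and single ones reached 0.31 in size at 2.5 days. The poly-A controls, 19 or 20 per pair, differed with SDs of 0.19, 0.12 and 0.21 at 12 hours, 2.5 and 4.5 days, and single ones by up to 0.64 at 12 hours and 0.72 at 4.5 days. The arrays at 2.5 and 4.5 days were the closest pair, with a robust SD of 0.15 over expressed genes, against 0.27, 0.35 and 0.39 for the 12-hour, 2.5-day and 4.5-day arrays against vehicle. Each gene list below is given by the median difference of its measured members. The first values in parentheses are the 95% interval of that median over the list's genes, and the percentile is its place among 10000 random lists matched on mean expression.

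Against vehicle, the 12-hour array had 122 genes at least 2-fold higher and 235 at least 2-fold lower among 12253 expressed genes. With a filter at the 75th percentile 76 were higher. The 10 highest differences belonged to digestive enzymes and a granule protein of the exocrine pancreas and to secreted lectins of the Reg family, and the lowest to genes of cornifying squamous epithelium, the tissue that lines the mouse forestomach. Apart from these, genes of the parietal cell list were lower, with 8 of 15 past 2-fold, the proton pump genes Atp4a and Atp4b not among the 8. At least 2-fold higher were 4 of 12 targets of NRF2 and 4 of 13 targets of ATF4. Slc7a11 was in both of these counts, and the ATF4 count also held Nupr1, a member of the wide pancreatic list. The median of mitotic genes lay below vehicle and that of DNA replication genes above it, with no member past 2-fold. The question this comparison addresses is what had changed shortly after tamoxifen.

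The 9 pancreatic acinar genes had a median difference of 6.54 at 12 hours (1.89 to 7.66, percentile 100), and 8 of them were at least 2-fold higher. Cela2a, an elastase, had a level of 13.62 at 12 hours and 4.29 in vehicle, a difference of 9.32. Among the other zymogen genes, Ctrb1 differed by 7.66, Ctrl by 7.41, Cpb1 by 7.25, Cpa1 by 7.17 and Prss2 by 6.54. Gp2, a zymogen granule protein, differed by 5.39. Genes of the Reg family of secreted lectins were among the largest increases too, with Reg3b at 7.51, Reg1 at 7.28 and Reg2 at 5.97. The acinar list was not higher at the other times, with medians of -0.48 (-1.39 to -0.20, percentile 0.07) at 2.5 days and -0.54 (-1.90 to -0.34, percentile 0.15) at 4.5 days. A colipase gene of this list, Clps, was at 14.67 in vehicle, and 5 of the 9 members were above the vehicle array's median. Of the 25 largest increases at 12 hours, 19 were in a wider list of pancreatic genes drawn up after the data were seen.

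The 10 squamous genes had a median of -2.65 at 12 hours (-5.97 to 0.07, percentile 0), with 8 at least 2-fold lower. The keratins Krt4 and Krt13 differed by -6.15 and -5.97, and Lor, which encodes the cornified envelope protein loricrin, by -5.32. Krtdap had the largest decrease, -7.15, followed by Rptn at -6.68. Of the 3 probe sets of Rptn only 1 was above the array median, and the probe set with the median absolute difference gave 0.10. The late cornified envelope genes Lce1f, Lce1d and Lce1c differed by -5.69, -5.34 and -5.30, Serpinb12 by -5.52 and Crct1 by -5.35. Sprr1a went the other way, at 1.14. At 2.5 and 4.5 days the squamous medians were 0.02 (-1.11 to 0.67, percentile 53.7) and 0.19 (-0.87 to 0.77, percentile 92.3), over members that went both ways. Krt4 was at -1.16 and -1.07 and Lor at -1.11 and -0.87, whereas the involucrin gene Ivl was at 1.98 and 1.54. With the probe set of median absolute difference Ivl was at -0.28 and -0.32, but of its 2 probe sets only 1 was above the array median. All 25 of the largest decreases at 12 hours were in a wider squamous list. As both wide lists were drawn up after the data were seen, these counts are not independent evidence. With both wide lists left out, an alternative also chosen after seeing the data, 95 genes were higher and 192 lower at 12 hours.

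**Figure D1:**
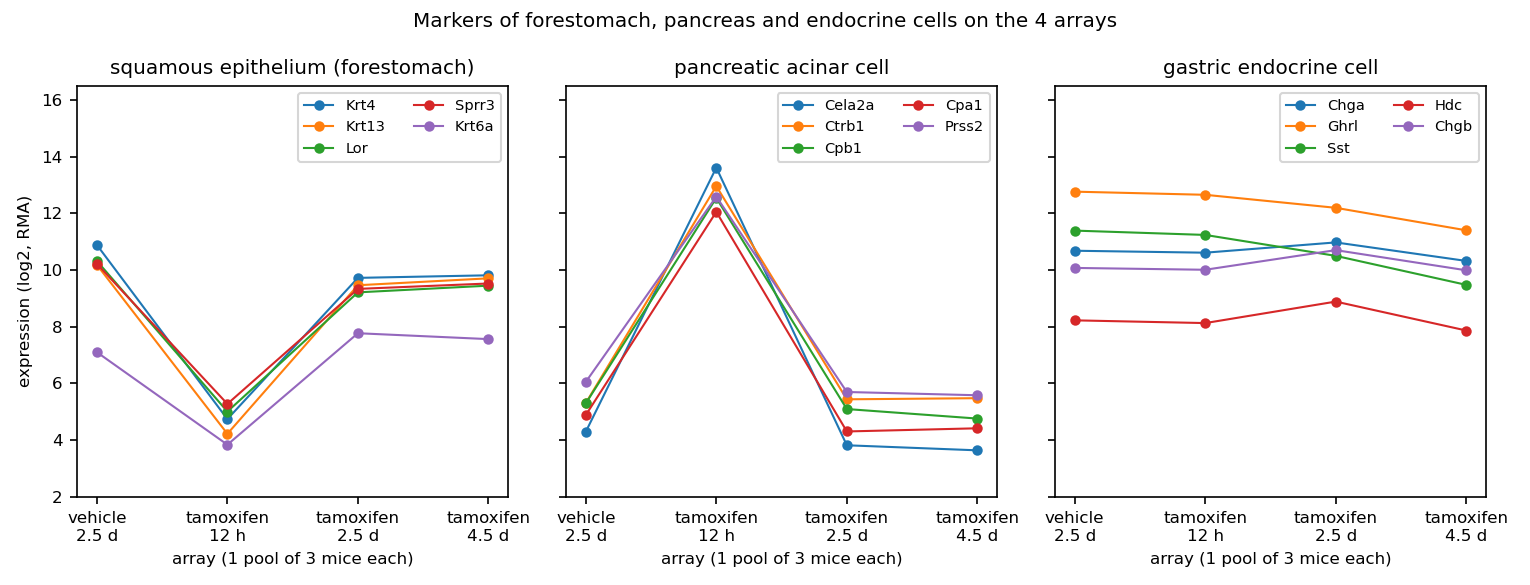
Log2 RMA expression (vertical axis) of 5 squamous epithelial, 5 pancreatic acinar and 5 gastric endocrine genes on the 4 arrays (horizontal axis), 1 point per array and a line per gene. The acinar genes stand far above vehicle on the 12-hour array alone (Cela2a 13.62 against 4.29) and the squamous genes far below it (Krt4 4.74 against 10.89), while the endocrine genes are close to vehicle there.

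Parietal cell genes had a median of -1.15 at 12 hours (-1.68 to -0.66, percentile 0), and 8 of 15 were at least 2-fold lower and none higher. Kcne2, a subunit of the potassium channel needed for acid secretion, differed by -2.85, the chloride and bicarbonate transporter Slc26a7 by -2.38, the water channel Aqp4 by -2.36 and the nuclear receptor gene Esrrg by -1.68. The proton pump genes Atp4a and Atp4b, at 13.38 and 14.19 in vehicle, differed by -0.66 and -0.95. These differences stood beside the acinar and squamous ones on the same array, where the 15 endocrine genes had a median of -0.10 (-0.18 to 0.11, percentile 14). Chief cell genes as a list had a median of -0.21 at 12 hours (-1.11 to 0.01, percentile 5.31). Of its 9 members 2 were past 2-fold: Bhlha15, the transcription factor of zymogen granule maturation, at -1.95, and Tnfrsf19 at -1.11. Both depended on the probe set, since the probe set with the median absolute difference gave 0.10 and 0.44. Of the 2 probe sets of Bhlha15 that was the one under the array median in vehicle. For Tnfrsf19 it was a dim probe set too, as only 1 of its 3 was above the array median in vehicle and at 12 hours. The zymogen genes Pgc, Pga5 and Cblif stayed at -0.17, -0.21 and -0.21.

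Targets of the transcription factor NRF2 had a median of 0.46 at 12 hours (0.02 to 1.70, percentile 100), with 4 of 12 at least 2-fold higher. Slc7a11, the cystine transporter, differed by 2.33 (its 2 probe sets by 1.02 and 2.33), the heme oxygenase gene Hmox1 by 1.91, the glutathione synthesis gene Gclc by 1.70 and Srxn1 by 1.52. Targets of ATF4 in the integrated stress response had a median of 0.80 (0.01 to 1.48, percentile 100), with 4 of 13 past 2-fold: Slc7a11 again, Nupr1 at 2.0, Atf3 at 1.48 and Psat1 at 1.03. Nupr1 is also abundant in pancreas and was in the wider pancreatic list. Immediate early genes had a median of 0.78 (0.43 to 1.09, percentile 100), led by Egr1 at 1.96, Atf3 and Myc at 1.09. The ER chaperone list lay lower, at -0.40 (-0.52 to -0.20, percentile 0), with Sdf2l1 at -0.65 and Creld2 at -0.63, and none of its 12 members passed 2-fold. Sqstm1, an autophagy receptor, was at 1.42, although its lysosome and autophagy list had a median of -0.08 (-0.24 to 0.08, percentile 24.9).

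The 17 mitotic genes had a median of -0.59 at 12 hours (-0.83 to -0.45, percentile 0), and the 18 replication genes a median of 0.47 (0.25 to 0.68, percentile 100). No member of either list passed 2-fold there. The kinases Bub1, Aurka and Aurkb were at -0.98, -0.90 and -0.88, whereas the replicative helicase gene Mcm4 was at 0.90 and the licensing factor gene Cdt1 at 0.77. Ribosome biogenesis genes had a median of 0.53 (0.18 to 0.64, percentile 100), with Nop58 at 1.01. Interferon response genes were at 0.77 (0.25 to 0.98, percentile 100), with Ifit1 at 1.22. Mucous neck and SPEM genes were at 0.20 (-0.21 to 0.99, percentile 99.9), with Slc7a11, the macrophage elastase gene Mmp12 at 1.96 and the chitinase-like gene Chil4 at 1.60 higher, and Cftr lower at -1.14. The 12-hour array differed from vehicle in both treatment and time of collection. The acinar and squamous shifts given above lay on that same array for each of these lists.

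At 2.5 days, where vehicle was taken at the same time, 408 genes were at least 2-fold higher and 238 at least 2-fold lower among 12295 expressed genes. With the filter at the 75th percentile 271 were higher. Most of the cell cycle, ribosome biogenesis and interferon response genes were at least 2-fold higher, as were 5 of 17 mucous neck and SPEM genes. Of parietal and chief cell genes, 9 of 15 and 5 of 9 were at least 2-fold lower. With 1 array on each side, this comparison shows how these pools differed.

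Reg3b had the largest increase at 2.5 days, 5.06, from 3.43 in vehicle to 8.49, and its 2 probe sets gave 2.68 and 5.06. Reg3g, another antimicrobial lectin of that family, differed by 2.74, on an array where the acinar list was below vehicle. The pantetheinase gene Vnn1 differed by 2.97, Slc7a11 by 2.71 and Atp6v0d2, a subunit of the vacuolar proton pump, by 2.74. The interleukin 1 receptor antagonist gene Il1rn differed by 2.87, the chitinase-like gene Chil3 by 2.84, Mmp12 by 2.81 and S100a8 by 2.77. The 3 probe sets of Il1rn ranged from 0.27 to 2.87 and the 2 of Slc7a11 from 1.43 to 2.71. Dscc1, which acts in sister chromatid cohesion, differed by 2.79.

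Among the largest decreases at 2.5 days, the secreted ribonuclease gene Rnase1 differed by -4.52 and the hepcidin gene Hamp2 by -3.91. B4galnt2, a glycosyltransferase, differed by -3.71, and Pdia2, a protein disulfide isomerase, by -3.70. Of the 4 probe sets of B4galnt2 the 3 above the array median ranged from -3.71 to -1.55. The apolipoprotein genes Apoa1 and Apoa4 differed by -3.51 and -3.28, the latter from 9.51 in vehicle. Slc26a7 differed by -3.38, the retinol dehydrogenase gene Rdh7 by -3.20, Gpr155 by -3.19 and the protease inhibitor gene Mug1 by -3.14. Rnase1 and Pdia2 are also pancreatic genes, and Rnase1 was 2.30 above vehicle on the 12-hour array.

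Parietal genes had a median of -1.10 at 2.5 days (-1.56 to -0.37, percentile 0), with 9 of 15 at least 2-fold lower. After Slc26a7 came Aqp4 at -3.05, Atp4b at -1.74 and Mfsd4a at -1.56. Chief cell genes had a median of -1.22 (-1.76 to 0.12, percentile 0), with 5 of 9 lower and 1 higher. The pepsinogen genes Pga5 and Pgc were at -2.29 and -1.27, the intrinsic factor gene Cblif at -1.68 and Bhlha15 at -1.76, while Tnfrsf19 was at 1.04. Mucous neck and SPEM genes had a median of 0.60 (0.13 to 1.15, percentile 100), with 5 of 17 higher, among them Mmp12, Slc7a11, the scavenger receptor gene Dmbt1 at 2.03 and the glutathione peroxidase gene Gpx2 at 1.39. Tff2, which encodes spasmolytic polypeptide itself, was at 14.10 in vehicle and -0.24 from it. Surface mucous genes had medians of 0.00 (-0.13 to 0.18), 0.02 (-0.47 to 0.10) and -0.08 (-0.47 to 0.07) at the 3 times. Their most abundant members, such as Gkn2 at 14.75 in vehicle, left little room above on this scale.

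Of 18 replication genes 16 were at least 2-fold higher at 2.5 days, with a median of 1.46 (1.14 to 1.65, percentile 100). The ribonucleotide reductase gene Rrm2 was at 2.27, and Ccne2 and Mcm5 were both at 1.92. Of 17 mitotic genes 16 were higher, with a median of 1.33 (1.19 to 1.63, percentile 100), led by Top2a at 1.80, Cdk1 at 1.73 and Bub1 at 1.71. Ribosome biogenesis genes had a median of 1.08 (0.69 to 1.29, percentile 100), with 8 of 14 higher, including nucleolin (Ncl) at 1.44 and Nop58 at 1.39. Cholesterol synthesis genes were at 0.51 (0.30 to 0.83, percentile 99.99), where Idi1, at 1.14, was the 1 member of 15 past 2-fold. Interferon response genes had a median of 1.62 (0.49 to 2.07, percentile 100), with 7 of 10 higher, such as Irf7 at 2.09, Ifit1 at 2.07 and Ifit3 at 1.98. The 12 macrophage and monocyte genes were at 0.77 (0.04 to 1.11, percentile 100), with Cd68 at 1.55, Cd14 at 1.16 and the complement genes C1qc and C1qa at 1.11 and 1.06. Of 8 neutrophil genes 2 were past 2-fold, S100a8 and S100a9 (1.12), but that list's median was 0.09 (-0.33 to 2.77, percentile 94.4). The 9 smooth muscle genes had a median of -0.77 (-0.85 to -0.48, percentile 0), after -0.43 (-0.57 to -0.16, percentile 0.04) at 12 hours, and none passed 2-fold. In vehicle Actg2 and Cnn1 of this list were at 12.42 and 11.27, so by these markers the pool was not epithelium alone. The squamous median was 0.02 here, with members past 2-fold on both sides.

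**Figure D2:**
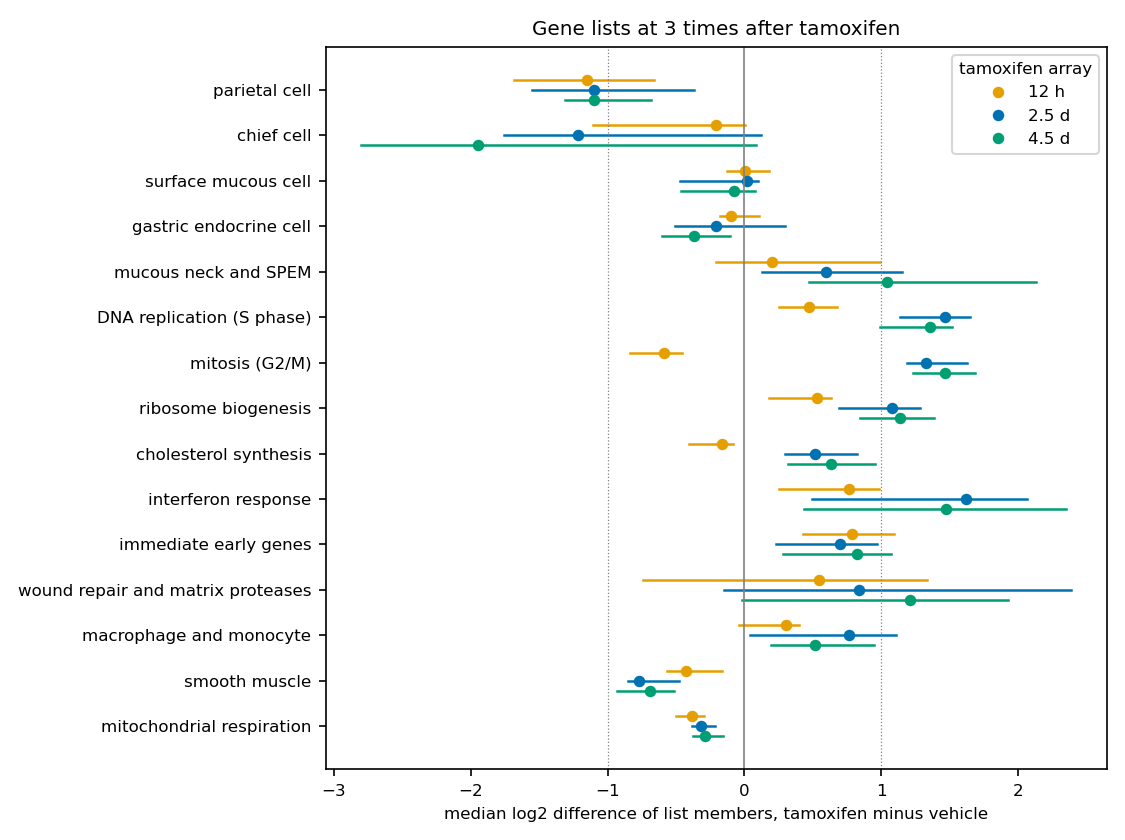
Median log2 difference from vehicle (horizontal axis) of 15 gene lists at 3 times after tamoxifen (12 hours, and 2.5 and 4.5 days), with a point per list and time and a bar for the 95% interval of the median over the list's genes, which says nothing of the spread between mice. Parietal medians are near -1.1 at each time, chief cell medians go from -0.21 to -1.95, and mitotic medians from -0.59 to 1.47; dotted lines mark 2-fold.

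At 4.5 days 468 genes were at least 2-fold higher and 335 at least 2-fold lower than vehicle among 12303 expressed genes. The median of chief cell genes lay further below vehicle than at 2.5 days, and those of SPEM and matrix protease genes further above. Cell cycle and interferon response genes were again higher as lists, and parietal genes lower. Vehicle was taken 2 days earlier than this array.

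The largest increases at 4.5 days were Reg3g at 4.0, from 4.86 to 8.86, and Vnn1 at 3.96, whose 2 probe sets gave 3.96 and 4.34. The mucosal mast cell protease gene Mcpt1 differed by 3.64, Slc7a11 by 3.42, the collagenase gene Mmp13 by 3.37 and Mmp12 by 3.32. Dmp1 differed by 3.30, Khdc1a by 3.08, Il1rn by 3.08 and Dscc1 by 2.83. Probe sets differed in size for Il1rn (0.30 to 3.08), Slc7a11 (1.49 to 3.42) and Dmp1 (1.5 to 3.44). Mug1 had the largest decrease, -4.68, followed by Slc26a7 at -4.37, Hamp2 at -4.32, B4galnt2 at -4.24 and Pdia2 at -3.84. The ubiquitin ligase gene Hecw2 differed by -3.54, Rnase1 by -3.50, the G protein-coupled estrogen receptor gene Gper1 by -3.44, Gpr155 by -3.43 and Pga5 by -3.41. Probe sets above the array median ranged from -4.24 to -1.69 for B4galnt2 and from -3.54 to -2.38 for Hecw2. In vehicle these decreasing genes were at 8.37 to 13.19.

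Chief cell genes had a median of -1.95 at 4.5 days (-2.80 to 0.09, percentile 0), with 6 of 9 at least 2-fold lower. After Pga5 came the acidic chitinase gene Chia1 at -2.80, Pgc at -2.44 and Cblif at -2.39, whereas Tnfrsf19 was at 1.41 and the vesicle gene Rab3d at -0.33. The parietal median was -1.10 (-1.31 to -0.68, percentile 0), with 9 of 15 lower. The gastrin receptor gene Cckbr was at -1.63, although its probe set with the median absolute difference gave 0.42, and Mfsd4a was at -1.62. Of the 2 probe sets of Cckbr only 1 was above the array median on the 2.5-day and 4.5-day arrays. Atp4b was at -1.31, and Aqp4 at -1.06, against -3.05 at 2.5 days. SPEM and mucous neck genes had a median of 1.04 (0.47 to 2.13, percentile 100), with 9 of 17 higher, none lower, and Cftr at 2.38, Gpx2 at 2.14 and Olfm4 at 2.13 among them. Endocrine genes were at -0.37 (-0.60 to -0.11, percentile 0.07), after -0.20 (-0.50 to 0.29, percentile 3.22) at 2.5 days. The somatostatin gene Sst was at -1.92 and the ghrelin gene Ghrl at -1.36, the 2 members past 2-fold.

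**Figure D3:**
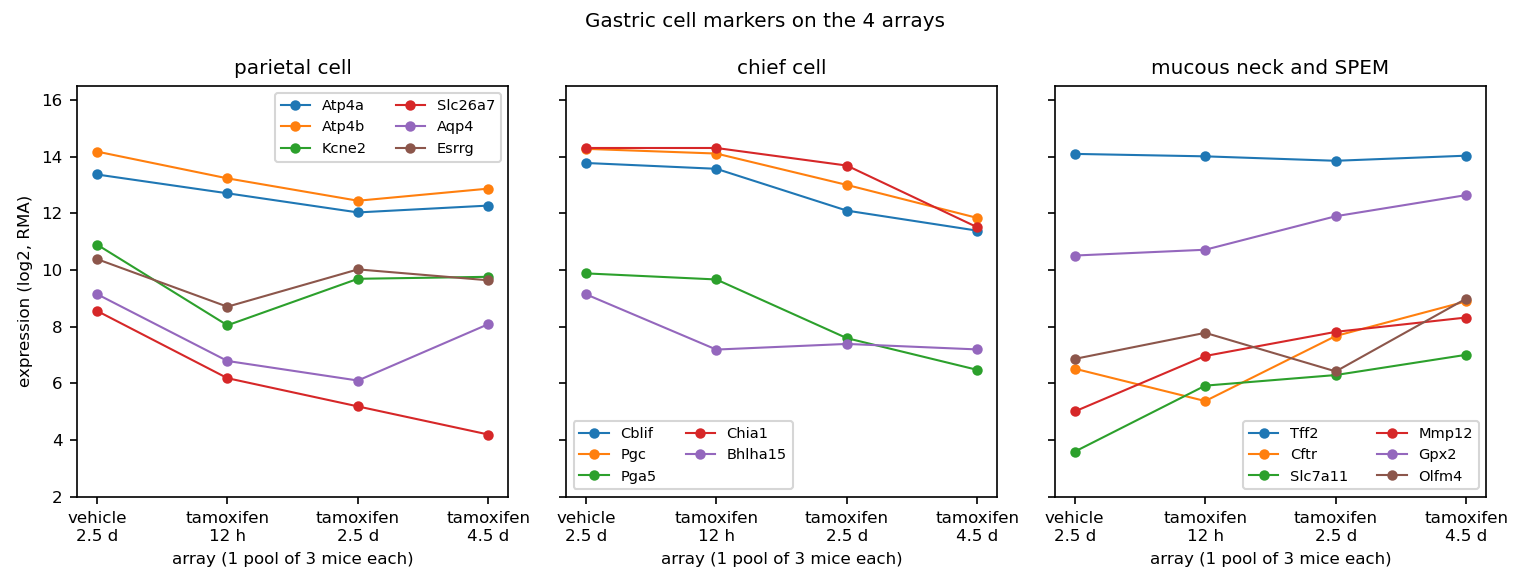
Log2 RMA expression (vertical axis) of parietal, chief, and mucous neck and SPEM genes on the 4 arrays (horizontal axis), 1 point per array and a line per gene. Kcne2 is lowest at 12 hours and Slc26a7 at 4.5 days, the zymogen genes Pgc and Pga5 are near vehicle at 12 hours and lowest at 4.5 days, and Tff2 lies near 14 on every array.

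Wound repair and matrix protease genes had medians of 0.54 (-0.74 to 1.34, percentile 100), 0.84 (-0.15 to 2.39, percentile 100) and 1.21 (-0.01 to 1.92, percentile 100) at the 3 times, with 4, 4 and 7 of 11 at least 2-fold higher. At 4.5 days the protease inhibitor gene Timp1 and Mmp10 were both at 1.92, and Mmp3 at 1.49. Mast cell genes had a median of 0.48 at 4.5 days (-0.94 to 2.37, percentile 99.9). The proteases Mcpt1, Mcpt2 (2.37) and Cma1 (1.47) were higher, whereas the receptor gene Kit was at -1.14 and the IgE receptor subunit gene Ms4a2 at -0.94. Replication and mitotic genes had medians of 1.36 (0.99 to 1.52, percentile 100) and 1.47 (1.23 to 1.68, percentile 100), with 13 of 18 and 16 of 17 at least 2-fold higher. Ribosome biogenesis genes were at 1.14 (0.85 to 1.38, percentile 100), cholesterol synthesis genes at 0.63 (0.32 to 0.95, percentile 100) and interferon response genes at 1.47 (0.43 to 2.35, percentile 100). Macrophage genes were at 0.51 (0.19 to 0.95, percentile 99.98), with Cd14 and Lyz2 at 1.46 and 1.38, and smooth muscle genes at -0.69 (-0.93 to -0.51, percentile 0).

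Epidermal growth factor and its relatives differed in direction within their list, whose medians were 0.04, 0.38 and 0.46 at the 3 times (percentiles 79.5, 98.5 and 99.4). Egf was at -1.53, -2.68 and -2.98, and Ereg, which encodes another ligand of the same receptor, at -0.51, 1.99 and 2.80. Nrg1 was at 0.25, 1.48 and 1.79, and the receptor gene Egfr at -0.04, -0.15 and 0.04. In the list of estrogen receptor and target genes the medians were -0.04, 0.22 and 0.26 (percentiles 40.5, 98.0 and 98.1). Its 1 member past 2-fold at 12 hours and 2.5 days was Gper1, at -2.56 and -2.81, and at 4.5 days Igf1 was also past it, at 1.05. The nuclear receptor genes Esr1 (4.81 in vehicle) and Esr2 were under the array median in vehicle, and differed from vehicle by at most 0.39 in size. In this list the 2.5-day median changed sign, to -0.11, with the probe set of median absolute difference.

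From 12 hours to 2.5 days, 315 genes were at least 2-fold higher and 80 at least 2-fold lower among 12205. The first count became 194 with the probe set of median absolute difference and 188 with the filter at the 75th percentile. The 5 largest increases were squamous genes (Krtdap at 6.61, Rptn at 5.54, Krt13 at 5.25, Krt6b at 5.13 and Krt4 at 4.99) and the 5 largest decreases pancreatic ones (Cela2a at -9.80, Cpa1 at -7.75, Ctrb1 at -7.53, Cpb1 at -7.45 and Ctrl at -7.35). With the probe set of median absolute difference Rptn turned to -0.27 over this step, where only 1 of its 3 probe sets was above the array median. Without the wide pancreatic and squamous lists 269 genes were higher and 53 lower. All 17 mitotic genes were at least 2-fold higher on the later array, with a median of 1.94 (1.85 to 2.11, percentile 100), and the replication median was 0.83 (0.78 to 1.10, percentile 100). Of these mitotic genes Aurka, at 2.21, turned to -0.35 with the probe set of median absolute difference. Of its 2 probe sets only 1, the one read here, was above the array median. Within the parietal list Kcne2 and Esrrg were higher, by 1.64 and 1.32, while Atp4b differed by -0.79 and Slc26a7 by -1.0.

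From 2.5 to 4.5 days 30 genes were at least 2-fold higher and 22 at least 2-fold lower among 12117, and 14 were higher with the filter at the 75th percentile. Simulated noise taken from this same pair put 0.37% to 0.51% of unchanged genes past 2-fold in the comparisons with vehicle. That noise held this pair's own differences, so a like share was fixed in advance. It cannot tell whether the 52 genes here exceed noise. The cytochrome P450 gene Cyp2c29 differed by 2.67, Olfm4 by 2.57, Mcpt1 by 2.23, Aqp4 by 1.99 and Ly6m by 1.76. The largest decreases were Chil3 at -2.58, the siderophore-binding lipocalin gene Lcn2 at -2.50, Reg3b at -2.41, Chia1 at -2.18 and S100a8 at -2.06. Chief cell genes had a median of -0.19 over this step (-1.17 to -0.03, percentile 0.25), with 3 of 9 at least 2-fold lower, endocrine genes -0.40 (-0.71 to 0.10, percentile 0) and SPEM genes 0.36 (0.18 to 0.72, percentile 100).

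Overlaps were counted among genes expressed in both comparisons, so these lists are in part shorter than those above. Of 12230 such genes, 400 and 452 were higher and 238 and 335 lower at 2.5 and 4.5 days. Of these, 329 were higher and 201 lower at both times, and none went opposite ways. Independent lists of these sizes would share 14.8 and 6.52 genes. Simulated unchanged arrays against 1 shared simulated array, all with the noise of the closest pair, shared 8.22 and 7.88. The 12-hour list of higher genes held 108 in the pair with 2.5 days and 105 in that with 4.5 days. The 12-hour and 2.5-day lists shared 60 higher and 127 lower genes, where independent lists would share 3.23 and 4.60, and the simulation 8.08 and 7.70. In that pair 7 genes were higher at 12 hours and lower at 2.5 days, and 2 the reverse. The 12-hour and 4.5-day lists shared 56 and 127, against 3.53 and 6.48 for independent lists and 8.0 and 7.66 in the simulation, with 4 higher and then lower and 3 the reverse. Across genes, which are not independent replicates, the differences at 2.5 and 4.5 days correlated at 0.93 (simulated 0.50), with a covariance of 0.25 (simulated 0.02). For 12 hours the correlation was 0.54 with 2.5 days and 0.49 with 4.5 days (simulated 0.50 for both), with covariances of 0.13 and 0.13 (simulated 0.02). The 1 vehicle array cannot be split, so part of each overlap may come from it. The simulation does not measure that part, because it assumed that the vehicle array was no noisier than the closest pair.

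Mitochondrial respiration genes were slightly below vehicle at all times, at -0.38 (-0.50 to -0.29, percentile 0), -0.32 (-0.39 to -0.21, percentile 0.01) and -0.29 (-0.37 to -0.15, percentile 0.08), and none of the 19 passed 2-fold. Fatty acid oxidation genes were at -0.05, -0.08 and -0.33, the last at percentile 0.22, and Pdk4 was at 1.71 at 12 hours. The later NRF2 medians were 0.47 and 0.50 (percentiles 99.97 and 99.96) and the later ATF4 medians 0.11 and 0.01, and Nupr1 was at -1.29 and -1.85. The ER chaperone medians were -0.14 and -0.13, and the lysosome and autophagy medians -0.15 and -0.14. Immediate early genes were at 0.70 and 0.82 (percentile 100 at both), with Egr1 at 1.88 and 1.53. The p53 target medians were 0.14 (percentile 97.7), 0.05 and 0.03, and Cdkn1a was within 0.26 of vehicle at each time.

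Cytokine and chemokine genes had medians of 0.36, 0.28 and 0.37 (percentile 100 at each time). The first became 0.68 over expressed members alone. Among them were Cxcl10 at 1.59 at 12 hours, Cxcl2 at 1.73 at 2.5 days and Il33 at 1.76 at 4.5 days. Xenobiotic metabolism genes were at -0.05, -0.06 and 0.00, although Cyp2b10, a target of the nuclear receptor CAR, was at 1.54 at 12 hours. Stem cell associated genes were at -0.09, 0.05 and 0.12, and circadian clock genes at -0.10, 0.12 and -0.06. Tuft cell genes were at 0.03, -0.41 (percentile 0.29) and 0.02, and intestinal genes at 0.10, -0.13 and -0.10, although Guca2a was at 2.30 at 4.5 days. Fibroblast genes were at -0.29 (percentile 0.88), -0.04 and 0.12, and endothelial genes at -0.06, -0.23 and -0.40 (percentile 0.68). Macrophage genes at 12 hours were at 0.30 (percentile 100).

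Neutrophil medians at 12 hours and 4.5 days were 0.19 and -0.20, and mast cell medians at 12 hours and 2.5 days 0.16 and 0.14. T and NK cell genes were at 0.05, -0.28 and -0.03, and B and plasma cell genes at -0.16, -0.38 (percentile 1.44) and -0.55 (percentile 0.13). Eosinophil genes were at 0.05, -0.12 and -0.13, and erythroid genes at 0.13, -0.26 and -0.18. Adipocyte and mesothelial genes were at -0.30 (percentile 0.57), -0.20 and 0.03, with the mesothelin gene Msln at 2.26 at 4.5 days. Enteric neuron and glia genes were at 0.17, -0.21 and -0.41, and the last, at percentile 1.26, turned to 0.094 with the probe set of median absolute difference. The cholesterol synthesis median at 12 hours was -0.16 (percentile 6.30). Sex-linked genes were at -0.24, -0.04 and -0.10, and the Y-linked gene Eif2s3y lay between 8.82 and 9.15 on the 4 arrays. Xist, at 4.89 to 5.06, was under the median of each array, so each pool held male RNA and little female RNA was seen. Reference genes, often taken as stable, were at 0.07, 0.27 and 0.48 (percentile 99.7), with Gusb at 0.96 at 4.5 days.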

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

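The tests on parietal genes and on mitotic and replication genes were chosen only after the results they measure were seen. The islet, second acinar and second squamous lists were written after the main acinar and squamous lists had been seen, but before their own values were. The bounds for the islet and second acinar lists were written before their values were seen and set aside afterwards, and the reading of the second acinar list was changed more than once after its value was seen. For the second squamous list the bound written beforehand was on the median alone, whereas the reading below also uses the interval.

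These results stood out because the 12-hour array differed from vehicle one way and the later arrays the other way. No test of the difference between times was possible with 1 array each. The mitotic median was -0.59 at 12 hours and 1.33 and 1.47 at 2.5 and 4.5 days. Tnfrsf19, a receptor gene of the chief cell and stem cell lists, was at -1.11, 1.04 and 1.41. With the probe set of median absolute difference its 12-hour value was 0.44. Only 1 of its 3 probe sets was above the array median on the vehicle, 12-hour and 2.5-day arrays, so the opposition of times rests on that 1. The chloride channel gene Cftr was at -1.14, 1.15 and 2.38. The alarmin gene Il33 was at -1.28, 0.73 and 1.76, and the keratin gene Krt16 at -1.03, 1.69 and 1.5. Nupr1 was at 2.0, -1.29 and -1.85. Of the genes also known from pancreas, Rnase1 was at 2.30, -4.52 and -3.50, Pnliprp1 at 2.47, -1.85 and -1.90, and Cel at 4.31, -1.39 and -1.52.

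Probe sets without exactly 1 gene symbol, which no gene count uses, also held differences from vehicle. At 12 hours 43 of 2943 expressed ones were at least 2-fold higher and 26 lower. At 2.5 days 74 of 2929 were higher and 29 lower, and at 4.5 days 103 of 2954 were higher and 44 lower.

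Pancreatic acinar genes were high and squamous genes low on the 12-hour array. The 7 islet genes, of which 2 were at or above the array median in vehicle, had a median of 0.11 there (-0.31 to 0.42), and the 8 genes of the second acinar list, less abundant in pancreas than zymogen genes, one of 0.34 (-1.40 to 0.94, percentile 99.9), both with intervals below the bound of 1 set beforehand. Those bounds assumed how far a share of pancreas would raise these genes, but pancreas itself was not analysed here, and a small share would hardly show on Cckar at 9.97 or Gnmt at 7.56 in vehicle. Pancreas carried into the 12-hour pool, with or without islets, therefore stays open as a candidate source and is not shown by these tests. The second squamous list was at -0.53 (-1.11 to -0.23), with 8 of 20 at least 2-fold lower and a median of 0.03 at 2.5 days. By the bound of -1 set beforehand on the median alone, this value counted against less forestomach in the 12-hour pool. The interval, which that bound did not mention, spans -1, so less forestomach is left open here. An untested response of the stomach to tamoxifen at 12 hours stays open too.

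Parietal cell genes had a median of -1.15 at 12 hours, with 8 of 15 at least 2-fold lower. Dilution by RNA of other tissue without endocrine transcripts would lower endocrine genes alike, and their median was -0.10 (-0.18 to 0.11), which argues against it. A lower share of parietal cells with unchanged expression in each would move all parietal genes alike between 12 hours and 2.5 days. Their differences over that step spanned 2.64, from -0.997 for Slc26a7 to 1.64 for Kcne2, with 2 members at least 1 higher and none at least 1 lower. This fell short of the bound of 2 each way, with Slc26a7 just inside it, so a change in cell share is neither shown nor excluded. A lower transcription of these genes within parietal cells, the biological alternative, stays open and untested.

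The mitotic median was below vehicle at 12 hours while the replication median was above it, with no gene of either list past 2-fold. Less forestomach epithelium in that pool, acting alone, would lower both. The replication median of 0.47 (0.25 to 0.68) argues against it as the only cause for replication genes. That rise was part of the pattern itself, and it cannot tell whether a loss lay beneath it. For mitotic genes, at -0.59 (-0.83 to -0.45), less forestomach stays open, because the share of their RNA that came from forestomach is unknown. Dilution by other tissue without endocrine transcripts is argued against by the endocrine median of -0.10 (-0.18 to 0.11). A change of the cell cycle after tamoxifen, the biological alternative, stays open and untested, since vehicle at 12 hours was not analysed here.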

How the results depend on the processing

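Only the alternatives named as such below were chosen after seeing the data. No paired analysis was possible because each group is 1 array. Repeated quantile normalization, removal of the loess trend, no filter, the mean of all probe sets and leaving out _s_at and _x_at probe sets kept all 10 counts of genes within 1.5 times. By construction other thresholds moved them. At 1.5-fold the genes higher and lower numbered 413 and 693 at 12 hours, 1191 and 741 at 2.5 days, 1322 and 1010 at 4.5 days, 918 and 278 from 12 hours to 2.5 days, and 113 and 142 from 2.5 to 4.5 days. At 3-fold they numbered, in the same order, 54 and 98, 106 and 72, 126 and 108, 139 and 42, and 7 and 6. At 3-fold the shared genes higher and lower were 17 and 25 for 12 hours and 2.5 days, 12 and 26 for 12 hours and 4.5 days, and 72 and 63 for 2.5 and 4.5 days. The filter at the 75th percentile, which tests fewer genes, left 76 higher at 12 hours, 271 at 2.5 days, 188 from 12 hours to 2.5 days and 14 from 2.5 to 4.5 days. The probe set with the median absolute difference gave 194 genes higher from 12 hours to 2.5 days, and the cause was not tested. Of the genes lower over that step, 53 were left without the wide pancreatic and squamous lists and 45 without genes apart on the 12-hour array, both chosen after seeing the data. Leaving out the wide lists was run on all 10 counts, leaving out genes apart on the 12-hour array on the 4 that use it, and choosing probe sets without that array, another later choice, on the other 6. None of these moved another of its counts by over 1.5 times.

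Of the list medians, 808 alternative values stayed inside the interval of the reported median, 8 lay outside it and 2 changed sign. The mitotic median at 12 hours became -0.44 with the mean of all probe sets and -0.44 with the probe set of median absolute difference, and at 2.5 days 1.19 and 1.18. With the latter probe set, the enteric neuron and glia median at 4.5 days became 0.094 and the estrogen receptor median at 2.5 days -0.11. Of the alternative values of named genes past 2-fold, 1408 kept their direction past 2-fold, 88 kept it under 2-fold and 14 changed sign. With the probe set of median absolute difference, Rptn became 0.10, Bhlha15 0.10 and Tnfrsf19 0.44 at 12 hours, Ivl -0.28 and Angptl4 -0.31 at 2.5 days, and Cckbr 0.42 and Ivl -0.32 at 4.5 days. From 12 hours to 2.5 days it gave Rptn -0.27, Aurka -0.35, Plau -0.13, Krt17 -0.29 and Dbp -0.023. Without _s_at and _x_at probe sets Angptl4 at 2.5 days was again -0.31 and Dbp over that step again -0.023. For Aurka, Plau, Krt17 and Dbp over that step, and for Ivl and Angptl4 at 2.5 days, only 1 of 2 probe sets was above the array median. Their changed values came from the dim probe set. The same holds for Rptn at 12 hours and over that step and for Tnfrsf19 at 12 hours, each with 1 of 3 probe sets above it. It also holds for Ivl and Cckbr at 4.5 days, each with 1 of 2 above it. For Bhlha15 at 12 hours the changed value came from a probe set that was under the array median in vehicle. The cause of the other changes was not tested. For genes whose dimmer value lies under its array's median, such as Cela2a at 4.29 in vehicle, the size of the difference depends on signal over background.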

Other observations

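All genes of this part outside the fixed lists were chosen after their values were seen. The secreted lectin genes of the Reg family followed different courses. Reg3b was at 7.51, 5.06 and 2.65 from vehicle at 12 hours and at 2.5 and 4.5 days, Reg1 at 7.28, 2.59 and 2.76, Reg2 at 5.97, -0.013 and 0.25, and Reg3g at 1.90, 2.74 and 4.0. Lcn2, an antimicrobial gene, was at 2.07, 1.97 and -0.53, and S100a8 at 1.36, 2.77 and 0.71, so both were within 2-fold of vehicle at 4.5 days. Over the same times Il1rn was at 2.53, 2.87 and 3.08, and Vnn1 at 1.18, 2.97 and 3.96.

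Some squamous and mucosal genes were above vehicle on the later arrays although the main squamous list's median was near it. In the second squamous list, whose median at 4.5 days was 0.18 (0.01 to 0.47, percentile 98.0), Krt16 was at 1.5, the annexin gene Anxa8 at 1.51 and Ly6d at 1.24. The islet medians at 2.5 and 4.5 days were -0.02 and -0.01, with the glucagon gene Gcg at -1.23 at 4.5 days, and the second acinar medians were -0.17 and -0.24. Cckar, a cholecystokinin receptor gene of that list, was at -1.40, -1.29 and -2.04 at the 3 times. Psat1 and Phgdh, which encode enzymes of serine synthesis, were at 1.03 and 0.80 at 12 hours, 2.12 and 0.98 at 2.5 days, and 2.46 and 1.17 at 4.5 days.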
